A study of Mus musculus with 18 samples.

How the data were processed

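RNA was measured in 18 libraries of OT-I CD8 T cells of the mouse (C57BL/6 background), which carry a transgenic receptor for an ovalbumin peptide. The cells had been transduced with guide RNAs and, per the labels, were null or wild type for Zc3h12a, the gene of the RNA-degrading protein Regnase-1. They were sorted from B16-Ova melanomas that express ovalbumin (tumour-infiltrating lymphocytes, TIL) or from peripheral lymph nodes (PLN). The libraries fell into 4 groups by the labels: wild-type PLN (n = 4), knockout PLN (n = 5), wild-type TIL (n = 4) and knockout TIL (n = 5). Per the labels, total RNA was quantified with RiboGreen and made into libraries with a stranded total RNA kit, so nuclear and non-polyadenylated RNA can enter the counts.

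The deposited files hold whole-number read counts per gene for each library, with no normalization. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, counted with HTSeq on the mouse genome build mm9, and compared by the authors with DESeq2 1.18.1; the aligner, the annotation release and the strand setting of the counting were not given in the sources used here. Reads shared with near-identical copies were partly dropped: of all reads in the deposited counts, 13.5 to 17.0% were listed as not unique, 21.6 to 27.3% as falling in no annotated feature and 1.76 to 2.02% as ambiguous between genes. The 5 summary lines that name no gene held 39.8 to 45.1% of reads and stayed out of library sizes and tests. Values of gene families with near-identical members (granzymes, killer lectin-like receptors, Lilrb4 and Gp49a, chemokines, ribosomal protein genes with processed pseudogenes) and of overlapping genes are therefore uncertain. Without a stated strand setting, reads of a gene and of an antisense neighbour may have been counted together. Positions are not given, because no annotation of build mm9 was used here.

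Gene counts summed to 10.9 to 58.6M per library. The files list 33924 genes, and 16051 passed edgeR's filterByExpr by group and were tested. Counts were normalized by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, in R 4.3.3) in a single model with a mean for each group over all 18 libraries (14 residual degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method at 0.05. CPM values used TMM library sizes. Fold changes are given as log2 ± standard error, the standard error being the size of the log2 fold change over the square root of the F statistic. The biological coefficient of variation was 9.69%. The labels do not say that the libraries of a group came from separate animals, so p-values measure only the spread between these samples. Each group carries its own sample code in the titles, and the labels name no batch. If the groups were handled separately, that handling would coincide with the group and could not be told apart from it. Each of the 32 pairs of libraries within a group differed by more than sampling noise (chi-square per gene 3.54 to 84.5), so no library was counted as a repeat.

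Comparisons were knockout against wild type in TIL and in PLN, TIL against PLN in wild type and in knockout, and the interaction (the knockout effect in TIL minus that in PLN). The 31 gene lists covered reported Regnase-1 targets, effector molecules, naive and memory T cells, exhaustion, tissue residency, AP-1 and IRF factors, NF-kappaB, nuclear-encoded and mitochondrially encoded respiratory chain genes, mitochondrial translation, glycolysis, cholesterol synthesis, S phase, mitosis, interferon response, the Bcl2 family, cytokine and chemokine receptors with integrins, interleukin-2 and STAT5 response, ribosomal proteins, the stress of tissue dissociation, nuclear RNA, and markers of melanoma, macrophages, dendritic cells, B cells, neutrophils, CD4 T cells, NK cells, stroma, red cells and T cells. Of 649 list entries, 640 matched a gene in the files, 6 of them by an older symbol (Gm13060 stands for Zfp683, the gene of Hobit). Lists with at least 5 measured members were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 lists tested, and again with an estimated correlation and with fry. The mean log2 CPM of each list was also compared between groups by exact two-sided permutation over all splits of the libraries.

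Named genes followed a rule: Zc3h12a and Batf in every comparison; the 8 largest rises and 8 largest falls (5 each way between tissues and for the interaction) among changed genes with a mean log2 CPM of at least 3 and, except for the interaction, no overlap between groups, leaving out predicted models, pseudogenes, small RNAs and receptor segments; and up to 4 changed members of a list by smallest p (3 between tissues and for the interaction), or up to 3 by level for cell type and technical lists. List members named outside that rule, mainly those that moved against the rest of their list, were chosen after their values were seen. Groups, lists and this naming rule were fixed before the data were examined. So were all alternatives except those named below as added, and the tests of the Results except the exact permutation of list levels. That permutation was not in the written plan.

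The test was checked on simulated counts drawn from the real means and library sizes, with 50 genes changed at each fold size. For knockout against wild type in TIL it recovered 46% of genes changed 1.3-fold, 74% changed 2-fold and 92% changed 4-fold. There were 3 false calls among 15842 genes, which made 2.14% of all calls. In PLN it recovered 28%, 76% and 96%, with 8 false calls among 15840. The simulation changed only 200 genes and gave all groups the same spread per gene. Real groups differ in both respects, so it does not compare the power in TIL with that in PLN. Alternatives were DESeq2 1.42.0, limma-voom, size factors, library size alone, no filter, a stricter filter (CPM of 1 in at least 4 libraries), a fold threshold, the comparison's own groups alone, the replicate number as a block, and leaving out each library in turn. An index of tumour RNA as a covariate, and leaving out 839 genes that followed it, were added after the data were seen. The index was the mean log2 CPM of Mlana, Tyr, Tyrp1, Dct and Slc45a2, and as a covariate it varied among TIL libraries only. Guide sequences and the edit itself were not analysed here. Some members of the cholesterol list are not reported here by name.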

Results

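Bulk RNA sequencing compared guide-transduced OT-I CD8 T cells labelled null for Zc3h12a (knockout) with wild-type cells, each recovered from melanomas (TIL) and from peripheral lymph nodes (PLN). Zc3h12a encodes Regnase-1, a ribonuclease that degrades messenger RNAs of inflammatory genes. The series asks how loss of Regnase-1 alters CD8 T cells in tumours and in lymph nodes, within a search by CRISPR for genes whose loss makes such cells longer-lived effectors. Gene counts averaged 23.1M ± 9.46 in wild-type PLN (SD, n = 4), 36.2M ± 5.02 in knockout PLN (SD, n = 5), 27.1M ± 16.2 in wild-type TIL (SD, n = 4) and 40.9M ± 14.2 in knockout TIL (SD, n = 5). The first principal component held 65.0% of the variance and separated the tissues, and the next held 14.9% and separated the genotypes. TIL knockout replicate 1 stood at 37.0 on the first component, between the tissues, against 62.3 to 70.1 for the other knockout TIL libraries.

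The Zc3h12a transcript itself was not lower in knockout libraries. It stood at 50.7, 48.7, 47.4 and 41.0 CPM in wild-type PLN and at 76.6, 72.2, 75.2, 72.3 and 72.6 CPM in knockout PLN. Wild-type TIL libraries held 67.2, 77.8, 70.0 and 55.5 CPM, and knockout TIL libraries 62.9, 87.9, 99.9, 72.9 and 69.2 CPM. In PLN it rose 1.56-fold with knockout (log2 fold change 0.65 ± 0.11, standard error, adjusted p = 9.5e-05), and in TIL the log2 fold change was 0.22 ± 0.11 (adjusted p = 0.135, and 0.0295 without TIL knockout replicate 1, in a range of 0.0295 to 0.392 over all alternatives). Counts per gene do not show a small edit in the coding sequence, so these levels neither show nor exclude loss of the protein. Batf, a transcription factor of the AP-1 family that works in effector T cell differentiation, rose in both tissues. It went from 49.0 ± 3.7 CPM (SD, n = 4) to 299 ± 14 CPM (SD, n = 5) in PLN, a 6.13-fold rise (log2 2.62 ± 0.06, adjusted p = 1.8e-17). In TIL it went from 52.9 ± 2.4 CPM (SD, n = 4) to 200 ± 13 CPM (SD, n = 5), a 3.77-fold rise (log2 1.92 ± 0.06, adjusted p = 1.2e-15). Every knockout library exceeded every wild-type library of its tissue.

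**Figure D1:**
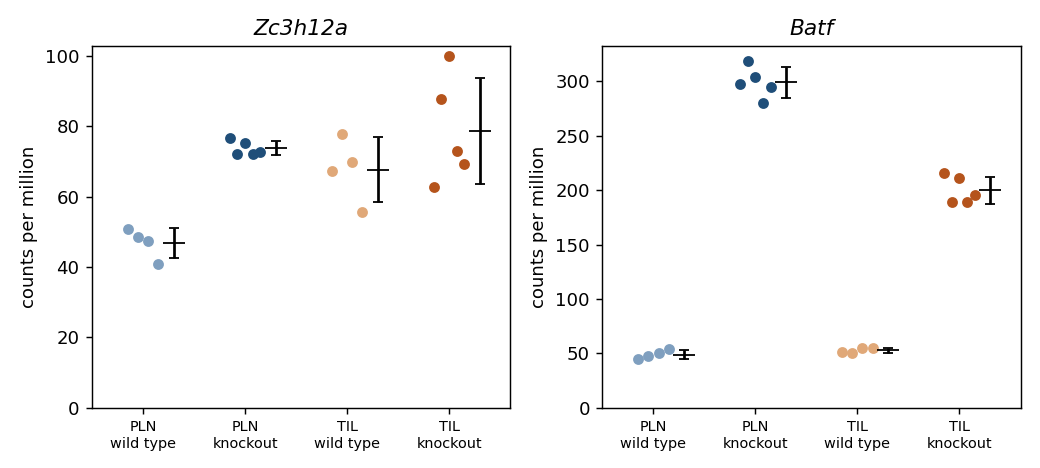
CPM of Zc3h12a and Batf in each library (dots) of the 4 groups, with the group mean and SD (black bars). Batf lies between 44.9 and 55.2 CPM in wild-type libraries and between 189 and 319 CPM in knockout libraries, while Zc3h12a is not lower in knockout libraries.

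In tumours, knockout cells carried far more RNA for Irak3, Pdzk1ip1, Prickle1 and Tnfrsf25 and less for Ccr2, Ccl5 and genes of the cell cycle (n = 4 wild-type and 5 knockout libraries). Irak3, a brake on Toll-like and interleukin-1 receptor signalling, rose from 2.98 to 145 CPM (log2 5.63 ± 0.15). Pdzk1ip1 (6.26 ± 0.19), Prickle1 of the planar polarity pathway (5.53 ± 0.12), Tnfrsf25, the death receptor that binds TL1A (5.48 ± 0.19), and Fam43a (5.07 ± 0.14) rose by similar amounts. Spock2, an extracellular matrix proteoglycan (3.98 ± 0.13), the cyclophilin Ppic (3.85 ± 0.09) and Cntnap1 (3.20 ± 0.22) followed. The largest falls among genes that met the naming rule were in the protease inhibitor Serpinb1a (−2.36 ± 0.13), the chemokine receptor Ccr2 (−2.17 ± 0.18, from 567 to 126 CPM), the adhesion molecule Amica1 (−1.92 ± 0.11), the inhibitory receptor Lilrb4 (−1.73 ± 0.06) and its near-identical relative Gp49a (−1.81 ± 0.08). Also lower were the urea transporter Slc14a1 (−1.76 ± 0.12), the NKG2A gene Klrc1 (−1.68 ± 0.11) and the chemokine Ccl5 (−1.58 ± 0.17, from 589 to 197 CPM). By edgeR's quasi-likelihood test 5270 of 16051 genes changed, 2860 higher and 2410 lower, and 842 of them by at least 1 on the log2 scale, 564 higher and 278 lower. With no filter on low counts 3069 were higher and 1573 lower.

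Genes of naive and memory T cells leaned up in knockout TIL, with 11 of 22 measured members higher and 2 lower, the same counts when adjusted over the list alone. Tcf7, which encodes the TCF-1 factor of stem-like T cells, rose from 161 to 480 CPM (log2 1.58 ± 0.11), with the surface receptor Slamf6 (1.92 ± 0.12), the B cell follicle homing receptor Cxcr5 (2.06 ± 0.16) and the TCF-1 relative Lef1 (0.60 ± 0.07). Bcl2, a survival gene, and Foxo1, a factor of quiescent cells, went the other way (−0.31 and −0.36). The camera test gave adjusted p = 0.00177 for this list, and adjusted p = 0.66 with an estimated correlation. Among 54 ribosomal protein genes 43 rose and none fell (48 and 0 adjusted over the list alone), with a median of 0.24, such as Rpl28 (0.35 ± 0.05), Rps25 (0.33 ± 0.05) and Rpl15 (0.36 ± 0.06). That list had adjusted p = 3.01e-10, and adjusted p = 0.66 with an estimated correlation.

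Cell cycle genes were lower in knockout TIL. Of 30 mitotic genes 27 fell and none rose (29 and 0 adjusted over the list alone). Among them were the kinetochore gene Cenpf (−1.19 ± 0.27), the proliferation marker Mki67 (−1.05 ± 0.25), the ubiquitin-conjugating enzyme Ube2c (−1.05 ± 0.25) and Cdca3 (−0.89 ± 0.22). Of 30 S phase genes 18 fell and none rose (24 and 0 adjusted over the list alone). They included the origin licensing factor Cdt1 (−0.53 ± 0.10), E2f1 (−0.85 ± 0.17), the replication clamp Pcna (−0.49 ± 0.11) and the primase Prim1 (−0.70 ± 0.16). The adjusted p was 9.43e-07 for mitosis and 2.76e-06 for S phase, and adjusted p = 0.804 for both with an estimated correlation. Mean log2 CPM of the mitotic list spread widely, 5.89 ± 0.49 in wild-type TIL (SD, n = 4) and 4.97 ± 0.76 in knockout TIL (SD, n = 5), down to 3.75 in TIL knockout replicate 1. The exact two-sided permutation test of these levels gave p = 0.0556. That replicate also held the least macrophage RNA (mean log2 CPM 1.79) and melanoma RNA (2.52) of the TIL libraries. The SD of the mitotic list was only 0.10 in wild-type PLN and 0.14 in knockout PLN. The model pooled the spread of each gene over all groups, so standard errors of mitotic genes in TIL may be too small.

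Cytokine and chemokine receptor and integrin genes fell more often than they rose, with 11 of 30 lower and 2 higher (13 and 3 adjusted over the list alone). Besides Ccr2, the interleukin-15 receptor chain Il15ra (−0.78 ± 0.07) and the TGF-beta receptor Tgfbr2 (−0.40 ± 0.05) fell. In contrast Ccr8, a chemokine receptor of skin-homing and regulatory T cells, rose (2.79 ± 0.26). The receptor and integrin list, called lower, had adjusted p = 0.0157, and adjusted p = 0.546 with an estimated correlation. T cell identity genes also leaned down, with 7 of 11 lower and 1 higher (8 and 1 adjusted over the list alone). Cd8a fell (−0.73 ± 0.05) by more than its partner chain Cd8b1 (−0.23 ± 0.04), Cd2 fell (−0.51), and the receptor kinase Zap70 rose (0.28). The Cd8b1 call was lost with no filter on low counts (adjusted p = 0.0514). The T cell identity list had adjusted p = 0.00109, and adjusted p = 0.454 with an estimated correlation.

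Several markers of other lymphocytes rose in these sorted CD8 T cells from knockout TIL. Of 5 CD4 T cell genes 3 rose and none fell (4 and 0 adjusted over the list alone), namely the CD40 ligand gene Cd40lg (3.66 ± 0.17), Zbtb7b, the factor that sets CD4 lineage (0.47 ± 0.08), and Il4, at the low level of 1.40 CPM in knockout TIL. Cd4 itself stood at 0.57 ± 0.25 (adjusted p = 0.096). The list had adjusted p = 0.00535, and adjusted p = 0.168 with an estimated correlation. Of 8 B cell genes 4 rose and none fell, the same counts when adjusted over the list alone: Cd22 (2.61 ± 0.19), Cd79b (2.57 ± 0.11), Ebf1 (2.99 ± 0.23) and Ighm (0.40 ± 0.05). The B cell list had adjusted p = 0.0333, and adjusted p = 0.332 with an estimated correlation. The call was lost without each of 9 libraries, namely TIL wild-type replicates 1, 3 and 4 (adjusted p = 0.142, 0.126 and 0.176), TIL knockout replicates 1 and 5 (0.0544 and 0.0517) and each of the 4 wild-type PLN replicates (0.0799 to 0.139).

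Camera did not call Regnase-1 targets, effector, exhaustion or residency genes in TIL. Of 15 reported Regnase-1 targets 7 rose and 3 fell (7 and 4 adjusted over the list alone; adjusted p = 0.288). The costimulator Icos (2.11 ± 0.11), the atypical inhibitor of NF-kappaB Nfkbiz (0.81 ± 0.06), the growth factor Il2 (1.67 ± 0.22) and Rel (1.15 ± 0.20) rose, and the early response genes Ier3 (−0.67) and Egr1 (−0.37) fell. Fry called the Regnase-1 targets higher (adjusted p = 0.0108), and exact permutation of list levels did not (adjusted p = 0.262). Among 25 effector genes 11 rose and 7 fell (adjusted p = 0.615). Klrg1, a receptor of terminal effectors (2.69 ± 0.27), the granzyme Gzmf (2.03 ± 0.24) and the cytokine Ifng (0.87 ± 0.14) rose, while Ccl5, Tnf (−0.78 ± 0.09) and the death ligand Fasl (−1.23) fell. Of 19 exhaustion genes 4 rose and 5 fell (4 and 8 adjusted over the list alone; adjusted p = 0.71). Ikzf2 (1.57 ± 0.06), Btla (1.58 ± 0.11) and Cd200 (1.304 ± 0.138) rose, and Cd160 (−0.84 ± 0.07) and the ectonucleotidase Entpd1 (−0.79) fell. For tissue residency 2 of 12 rose and 5 fell (adjusted p = 0.0539). Fry called the residency list lower (adjusted p = 5.83e-05). The falls included the Hobit gene under its older symbol Gm13060 (−2.14 ± 0.11), Cd101 (−1.50 ± 0.08) and Runx3 (−0.55 ± 0.10), and Cd69 rose (0.36 ± 0.08). Counts adjusted over the list alone were the same for effector and residency genes.

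Further lists in TIL gave 6 higher and 4 lower of 21 AP-1 and IRF factors (7 and 6 adjusted over the list alone). Irf4 fell (−1.09 ± 0.07), and Maf (2.45 ± 0.23) and Myc (0.54 ± 0.09) rose. Of 20 NF-kappaB genes 8 rose and 6 fell (9 and 7 adjusted over the list alone). Tnfaip8 (0.77 ± 0.05) and Cd83 (1.67 ± 0.22) rose, and Nfkbie fell (−0.84 ± 0.09). Of 15 Bcl2 family genes 4 rose and 3 fell (4 and 4 adjusted over the list alone). The rises included both the death-promoting Bmf (2.43 ± 0.14) and the survival gene Bcl2l1 (1.12 ± 0.13), and the death-promoting Bcl2l11 fell (−0.76 ± 0.07). Interleukin-2 and STAT5 genes gave 6 higher and 5 lower of 18 (6 and 7 adjusted over the list alone), with the kinase Pim2 (1.27 ± 0.08) and the signalling inhibitor Socs3 (0.70 ± 0.13) higher. Interferon response genes gave 5 higher and 6 lower of 27, the same counts when adjusted over the list alone, with Oas1a higher (1.15 ± 0.09) and Ifit2 lower (−0.89 ± 0.07). Of 22 glycolysis genes 7 rose and 1 fell (7 and 2 adjusted over the list alone), among them hexokinase Hk2 (0.92 ± 0.12), Aldoc (0.73 ± 0.11) and Pdk1 (0.40 ± 0.06). Nuclear-encoded respiratory chain genes gave 13 higher and 1 lower of 77 (9 and 1 adjusted over the list alone), mitochondrially encoded ones 1 higher of 11 (mt-Co3, 0.58 ± 0.19; 0 adjusted over the list alone, 2 at an unadjusted p under 0.05). The mt-Co3 call was lost without TIL wild-type replicate 2, 3 or 4 or TIL knockout replicate 2 or 3 (adjusted p = 0.0619 to 0.0701), with limma-voom (adjusted p = 0.0758) and with only the groups compared (adjusted p = 0.0946). Mitochondrial translation gave 10 higher and 1 lower of 45 (6 and 1 adjusted over the list alone). Cholesterol genes gave 2 higher and 1 lower of 21 (2 and 0 adjusted over the list alone) and dissociation stress genes 2 and 3 of 20. None of these lists was called by camera (adjusted p = 0.134 to 0.849).

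Among the remaining cell type lists in TIL, 1 of 12 melanoma genes rose (Trpm1, 0.46; 0 adjusted over the list alone) and 1 of 11 dendritic cell genes rose and 1 fell (Xcr1, 0.75, and Itgax, −1.36 ± 0.18). NK cell genes gave 2 lower of 6, stroma 1 higher and 1 lower of 8, and the neutrophil list 1 higher of 4 (Mmp9, 2.25 ± 0.29), too few members to test. By edgeR no member was called for macrophages (of 14; 0 at an unadjusted p under 0.05), red cells (of 5; 0 at an unadjusted p under 0.05) or nuclear RNA (of 6; 1 at an unadjusted p under 0.05), and none of these lists was called by camera (adjusted p = 0.134 to 0.71). Median, mean and test differed in sign in TIL for Regnase-1 targets, exhaustion, AP-1 and IRF factors, cholesterol, interferon response, the Bcl2 family, interleukin-2 and STAT5 genes and stroma, none of them called by camera. Of the 8 lists called in TIL none held with an estimated correlation (2 of 30 had an unadjusted p under 0.05), and fry called 14. Among lists that camera did not call, fry also called NK cell genes lower (adjusted p = 5.83e-05). It called stroma (adjusted p = 0.0338), AP-1 and IRF factors and the Bcl2 family (each adjusted p = 0.0436) higher. Exact permutation of list levels called 0 of 31 after adjustment (lowest adjusted p = 0.0615, with 10 at an unadjusted p under 0.05). The smallest unadjusted p that its 126 splits allow is 0.00794. The residency, B cell, CD4 T cell and T cell identity lists reached it, with no overlap between genotypes.

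In lymph nodes, knockout cells carried far more RNA for Irak3 and for several genes of cytotoxic effectors (n = 4 wild-type and 5 knockout libraries). Irak3 rose from 0.26 to 81.0 CPM (log2 8.24 ± 0.21), and Prickle1 (6.98 ± 0.13), Pdzk1ip1 (6.33 ± 0.18), Fam43a (5.19 ± 0.16) and Spock2 (5.0003 ± 0.144) rose as in TIL. The 2B4 receptor gene Cd244 (5.13 ± 0.18), the collagen-binding integrin Itga1 (4.76 ± 0.24) and granzyme B, Gzmb (4.47 ± 0.27, from 14.2 to 319 CPM), were among the 8 largest rises by the naming rule. Among genes that met the naming rule the largest falls were in Lilrb4 (−3.04 ± 0.09) and Gp49a (−2.39 ± 0.12), the chemokines Ccl4 (−2.52 ± 0.18) and Xcl1 (−2.33 ± 0.16), the costimulator Tnfrsf9 (−1.93 ± 0.14), Ctla2a (−1.87 ± 0.09), the death-promoting Bbc3 (−1.84 ± 0.11) and the CD94 gene Klrd1 (−1.84 ± 0.09). By edgeR's quasi-likelihood test 5680 genes changed, 3114 higher and 2566 lower, and 1274 of them by at least 1 on the log2 scale, 932 higher and 342 lower.

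Effector and exhaustion genes leaned up in knockout PLN. Of 25 effector genes 12 rose and 4 fell, the same counts when adjusted over the list alone. Il2 (3.55 ± 0.20), Gzmb, Ifng (1.996) and Gzma (3.88) rose, and Xcl1, Ccl4, Gzmm (−1.15) and Nkg7 (−0.27) fell. Of 19 exhaustion genes 11 rose and 3 fell (11 and 4 adjusted over the list alone), with the PD-1 gene Pdcd1 rising from 23.3 to 88.3 CPM (1.92 ± 0.12) and the TIM-3 gene Havcr2 by 3.29 ± 0.27. Both lists had adjusted p = 0.0393, and adjusted p = 0.875 for effector and 0.794 for exhaustion genes with an estimated correlation. The effector call was lost without PLN wild-type replicate 3 (adjusted p = 0.0503) or PLN knockout replicate 2 or 3 (0.0564 and 0.0570). The exhaustion call was lost without PLN wild-type replicate 3 (0.0509) or TIL knockout replicate 1 (0.0545).

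Mitotic genes were higher in knockout PLN, with 24 of 30 higher and none lower (30 and 0 adjusted over the list alone), among them Ccnb1 (1.56 ± 0.26), Ccnb2 (1.46 ± 0.24), the checkpoint kinase Bub1b (1.37 ± 0.25) and the centromeric histone Cenpa (0.67 ± 0.11). The list had adjusted p = 4.82e-06, and adjusted p = 0.875 with an estimated correlation. Its mean log2 CPM was 3.51 ± 0.10 in wild-type PLN (SD, n = 4) and 4.52 ± 0.14 in knockout PLN (SD, n = 5). S phase genes gave 7 higher and 3 lower of 30, the same counts when adjusted over the list alone, with cyclin genes Ccne1 (0.67 ± 0.08) and Ccne2 (1.06 ± 0.20) higher (adjusted p = 0.18). Ribosomal protein genes went down, with 51 of 54 lower and none higher (52 and 0 adjusted over the list alone), a median of −0.42, and examples in Rps19 (−0.75 ± 0.08), Rpl5 (−0.54 ± 0.05) and Rpl14 (−0.53 ± 0.04). That list had adjusted p = 7.06e-23, and adjusted p = 0.684 with an estimated correlation.

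**Figure D2:**
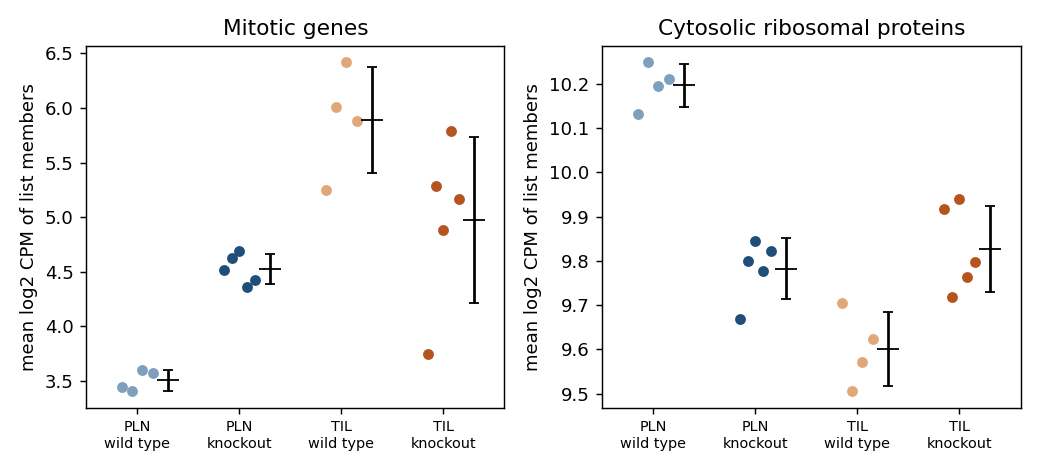
Mean log2 CPM of the mitotic and ribosomal protein lists in each library (dots) of the 4 groups, with the group mean and SD (black bars). Mitotic genes go from 3.51 to 4.52 with knockout in PLN and from 5.89 to 4.97 in TIL, where TIL knockout replicate 1 is lowest at 3.75, and ribosomal protein genes go from 10.20 to 9.78 in PLN and from 9.60 to 9.83 in TIL.

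Cholesterol genes rose in knockout PLN, with 13 of 21 higher and none lower, the same counts when adjusted over the list alone. They included squalene synthase Fdft1 (0.48 ± 0.07) and the transcriptional regulator of the pathway, Srebf2 (0.41 ± 0.08). The list had adjusted p = 0.000239, and adjusted p = 0.875 with an estimated correlation. Of 27 interferon response genes 15 rose and 2 fell (16 and 2 adjusted over the list alone), with Oas1a (1.33 ± 0.10), Cmpk2 (0.71 ± 0.09) and the antiviral gene Rsad2 (0.85 ± 0.12) higher (adjusted p = 0.00298, and adjusted p = 0.909 with an estimated correlation). Genes of dissociation stress fell, with 8 of 20 lower and none higher, the same counts when adjusted over the list alone, such as Dusp1 (−0.90 ± 0.13) and Jun (−0.62 ± 0.12). Their adjusted p was 0.00704, and adjusted p = 0.875 with an estimated correlation.

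Of 5 CD4 T cell genes 3 rose and none fell in knockout PLN, the same counts when adjusted over the list alone: Cd40lg went from 0.179 to 16.1 CPM (6.31 ± 0.20), Cd4 from 1.69 to 9.40 CPM (2.53 ± 0.21), and Zbtb7b rose by 1.96 ± 0.09. The list had adjusted p = 0.00243, and adjusted p = 0.0882 with an estimated correlation. Of 8 B cell genes 4 rose and none fell, the same counts when adjusted over the list alone, led by Cd79b (1.49 ± 0.09) and Ebf1 (1.27 ± 0.29), with adjusted p = 0.121. T cell identity genes gave 5 lower and none higher of 11 (6 and 0 adjusted over the list alone; adjusted p = 0.0588), with Cd8a at −0.46 ± 0.05, Cd8b1 at −0.14 ± 0.04 and Cd2 at −0.59. The Cd8b1 call was lost without PLN wild-type replicate 3 (adjusted p = 0.0505) and with no filter on low counts (adjusted p = 0.22).

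Camera did not call Regnase-1 targets, naive and memory, residency, AP-1 and IRF, NF-kappaB, receptor and integrin, Bcl2 family or interleukin-2 and STAT5 genes in PLN. Of 15 Regnase-1 targets 5 rose and 3 fell (5 and 4 adjusted over the list alone; adjusted p = 0.371), with Nfkbiz (1.48 ± 0.07), Il2 and Icos (1.502 ± 0.106) higher and Ier3 lower (−1.20). The Regnase-1 targets were called higher by fry (adjusted p = 0.00136) and by exact permutation of list levels (adjusted p = 0.0176). Their mean log2 fold change was 0.59 and their median 0.07. Naive and memory genes gave 6 higher and 13 lower of 22, the same counts when adjusted over the list alone (adjusted p = 0.138). Exact permutation called that list lower (adjusted p = 0.0176), and fry did not call it (adjusted p = 0.128). Slamf6 (1.38 ± 0.11) and Tcf7 (0.46) rose, and the quiescence factor Klf3 (−0.74 ± 0.08), Igfbp4 (−2.08 ± 0.25) and the chromatin organizer Satb1 (−0.62 ± 0.07) fell. For tissue residency 4 of 12 rose and 5 fell, also adjusted over the list alone (adjusted p = 0.877). Fry (adjusted p = 0.0181) and exact permutation of list levels (adjusted p = 0.0289) called the residency list higher. Its mean log2 fold change was 0.37 and its median −0.29. Itga1, the chemokine receptor Cxcr6 (1.15 ± 0.10) and Blimp-1, Prdm1 (2.04 ± 0.23), rose and Hic1 fell (−1.54 ± 0.20). AP-1 and IRF factors gave 5 higher and 6 lower of 21 (6 and 7 adjusted over the list alone), with Nfatc1 higher (1.11 ± 0.07) and Irf4 (−1.61 ± 0.07) and Eomes (−1.39 ± 0.09) lower. NF-kappaB genes gave 4 higher and 10 lower of 20, also adjusted over the list alone, with Bcl3 higher (0.97 ± 0.08) and Relb lower (−1.17 ± 0.09). Of 30 receptor and integrin genes 9 rose and 10 fell (10 and 12 adjusted over the list alone), with the integrins Itgb1 (1.36 ± 0.06) and Itga4 (1.48 ± 0.13) and the receptor Il12rb1 (0.97 ± 0.09) higher. Bcl2 family genes gave 4 higher and 3 lower of 15 (5 and 3 adjusted over the list alone), with Bmf (3.30 ± 0.14) and Bcl2l1 (0.80 ± 0.13) higher. Interleukin-2 and STAT5 genes gave 7 higher and 4 lower of 18 (7 and 6 adjusted over the list alone), with Pim2 (1.56 ± 0.08) higher and Tnfrsf18 lower (−0.996 ± 0.087).

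Glycolysis gave 8 higher and 2 lower of 22 (9 and 2 adjusted over the list alone; adjusted p = 0.117), with Aldoc (1.34 ± 0.15), Gapdh (0.50 ± 0.07) and Hk2 (0.89 ± 0.13) higher in knockout PLN. Nuclear-encoded respiratory chain genes gave 16 higher and 4 lower of 77 (12 and 3 adjusted over the list alone) and mitochondrial translation 2 higher and 7 lower of 45 (2 and 5 adjusted over the list alone). No mitochondrially encoded gene of 11 was called by edgeR (1 at an unadjusted p under 0.05, mt-Cytb 0.33 ± 0.13, adjusted p = 0.065). Melanoma markers gave 1 higher of 12 (Trpm1, 2.37 ± 0.18), macrophages 1 of 14 (Cd68, 0.55 ± 0.12), stroma 1 of 8 (Pecam1, 1.38 ± 0.09), and dendritic cells 2 higher and 2 lower of 11, with Xcr1 at 3.95 ± 0.15 and Itgax at 0.89 ± 0.19. NK cell genes gave 1 higher and 2 lower of 6 and nuclear RNA 1 higher and 2 lower of 6 (Malat1 0.30 ± 0.09, Gas5 −0.29 ± 0.06), and by edgeR no neutrophil or red cell gene was called (0 at an unadjusted p under 0.05). For the lists given here without a p from camera, camera gave adjusted p = 0.18 to 0.937. Median, mean and test differed in sign in PLN for residency, AP-1 and IRF factors, the Bcl2 family, receptors, interleukin-2 and STAT5 genes and dendritic cells, none of them called by camera. Of the 8 lists called in PLN none held with an estimated correlation (2 of 30 had an unadjusted p under 0.05), fry called 19 and exact permutation of list levels 17 of 31 after adjustment (adjusted p = 0.0176 or 0.0289). Among lists that camera did not call, permutation also called NF-kappaB, NK cell and T cell identity genes lower. It called glycolysis, mitochondrially encoded, S phase, and interleukin-2 and STAT5 genes higher. The dissociation stress list, called by camera, was not called by permutation (adjusted p = 0.0547).

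Many genes moved the same way with knockout in both tissues. Among genes tested, 1251 rose in both, where independent lists of these sizes would share 555, and 692 fell in both against 385. Another 390 and 400 changed in opposite directions, against 457 and 468 for independent lists. Irak3, Pdzk1ip1, Prickle1, Fam43a and Spock2 were among the 8 largest rises of both tissues by the naming rule, and Lilrb4 and Gp49a among the 8 largest falls of both. The log2 fold changes correlated across genes with Pearson's r = 0.46 and Spearman's rho = 0.23, genes not being independent replicates, and the comparisons shared no library. They did share the model's estimate of each gene's spread, which can raise the overlap of calls in either direction. Opposite changes nonetheless lay under the numbers for independent lists. Of the 1943 genes that moved the same way, 537 also differed in size by the interaction test, 335 of them with the larger effect in PLN.

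**Figure D3:**
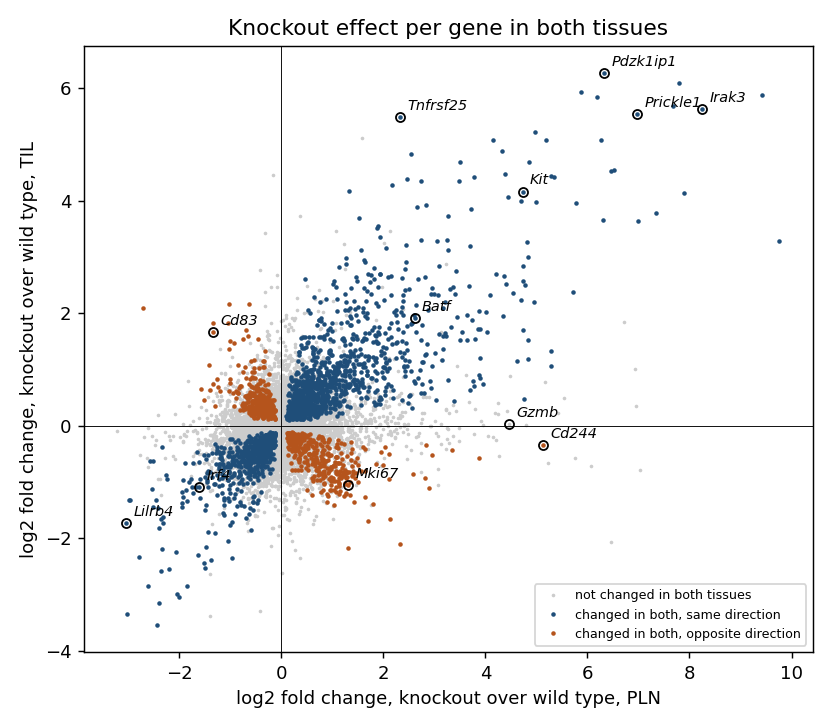
Log2 fold change with knockout in PLN (x axis) and in TIL (y axis) for each gene, with genes changed in the same direction in blue, in opposite directions in orange and others in grey. Batf, Irak3 and Prickle1 lie far up in both tissues, while Gzmb and Cd244 lie far to the right only, with interaction values of −4.44 and −5.48.

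The interaction tests whether knockout acted differently in TIL and PLN, and 4366 genes differed, 2049 with a higher and 2317 with a lower value in TIL. With library size alone the balance turned (2264 higher, 2102 lower), and at a log2 value of at least 1 it was 392 higher and 771 lower. The effect on Cd244 (−5.48 ± 0.21), Gzmb (−4.44 ± 0.33), Itga1 (−4.29 ± 0.28), Chn2 (−3.97 ± 0.25) and the calcium-binding S100a4 (−3.79 ± 0.17) was far lower in TIL than in PLN. It was higher in TIL for Tnfrsf25 (3.15 ± 0.24), the activation marker Cd83 (3.01 ± 0.29), Ccl4 (2.35 ± 0.22), the Notch regulator Dtx1 (2.24 ± 0.21) and Cd22 (2.14 ± 0.23). Batf differed by −0.70 ± 0.08 (adjusted p = 1.7e-06) and Zc3h12a by −0.43 ± 0.15 (adjusted p = 0.043), a call lost without any of 14 of the 18 libraries (adjusted p = 0.0546 to 0.102), the exceptions being PLN wild-type replicate 1, TIL wild-type replicate 4 and TIL knockout replicates 2 and 3 (0.00506 to 0.0436).

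All 30 mitotic genes had a lower effect in TIL, also adjusted over the list alone, such as Mki67 (−2.37 ± 0.36) and Ccnb2 (−2.09 ± 0.32). Mitosis had adjusted p = 3.85e-13, and adjusted p = 0.732 with an estimated correlation. S phase genes gave 0 higher and 20 lower of 30 (0 and 25 adjusted over the list alone), such as Ccne1 (−0.89 ± 0.12). S phase had adjusted p = 2.25e-06, and adjusted p = 0.793 with an estimated correlation. Ribosomal protein genes gave 53 higher of 54, also adjusted over the list alone, such as Rpl5 (0.72 ± 0.07). Ribosomal proteins had adjusted p = 4.01e-34, and adjusted p = 0.557 with an estimated correlation. Naive and memory genes gave 15 higher and 1 lower of 22, also adjusted over the list alone, such as Satb1 (1.12 ± 0.11), Tcf7 (1.12 ± 0.15) and Lef1 (0.90 ± 0.10). Naive and memory genes had adjusted p = 5.99e-06, and adjusted p = 0.722 with an estimated correlation. Cholesterol genes gave 10 lower of 21 (12 adjusted over the list alone), such as Sc5d (−0.57) and Fdft1 (−0.48). Cholesterol had adjusted p = 0.00186, and adjusted p = 0.732 with an estimated correlation. Interferon genes gave 12 lower of 27 (13 adjusted over the list alone), such as Oas3 (−0.55). Interferon response had adjusted p = 0.000781, and adjusted p = 0.879 with an estimated correlation. It was not called with fry (adjusted p = 0.0563). Tissue residency gave 3 higher and 6 lower of 12, also adjusted over the list alone, led by Itga1, Prdm1 (−2.41 ± 0.26) and Gm13060 (−1.94 ± 0.16). Residency had adjusted p = 0.0468, and adjusted p = 0.732 with an estimated correlation. That call was lost without PLN wild-type replicate 1 or 4, PLN knockout replicate 2 or 5, TIL wild-type replicate 1 or 2, or TIL knockout replicate 1, 4 or 5 (adjusted p = 0.0514 to 0.0702). It was also lost with the stricter filter (adjusted p = 0.0536) and with the tumour RNA index as a covariate (adjusted p = 0.0732).

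Several lists had no interaction call but large single genes. Effector genes gave 5 higher and 12 lower of 25 (6 and 13 adjusted over the list alone; adjusted p = 0.0862), with the fractalkine receptor Cx3cr1 at −3.29. Exhaustion gave 4 higher and 9 lower of 19 (adjusted p = 0.104), with Havcr2 at −3.60 ± 0.32 and Pdcd1 at −1.78 ± 0.16. Receptors and integrins gave 4 higher and 10 lower of 30 (5 and 10 adjusted over the list alone; adjusted p = 0.0862), with Ccr2 at −3.49 ± 0.28 and Itgb1 at −1.65 ± 0.09. All 3 CD4 T cell genes that differed were lower in effect in TIL, Cd40lg at −2.65, Cd4 at −1.96 and Zbtb7b at −1.50 (adjusted p = 0.0862). Median, mean and test differed in sign for Regnase-1 targets, AP-1 and IRF factors, nuclear-encoded respiratory chain genes, the Bcl2 family, interleukin-2 and STAT5 genes, nuclear RNA, B cells and red cells, none of them called.

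Wild-type cells from tumours differed from those of lymph nodes in most genes (n = 4 and 4 libraries). The TIM-3 gene Havcr2 (log2 7.58 ± 0.26), Gzmb (7.49 ± 0.30, from 14.2 to 2593 CPM), Cd244 (7.26 ± 0.18), the G protein regulator Rgs16 (6.47 ± 0.20) and the chemokine Ccl3 (6.35 ± 0.25) rose most among genes of the naming rule. Dtx1 (−5.88 ± 0.17), Cd22 (−5.22 ± 0.18), Fam101b (−5.04 ± 0.16), Tnfrsf25 (−4.50 ± 0.20) and the epithelial-binding integrin Itgae (−3.99 ± 0.16) fell most among them. By edgeR's quasi-likelihood test 11113 genes changed, 5561 higher and 5552 lower. The balance moved with the scaling (4966 higher and 6294 lower with library size alone, 5822 and 5275 with size factors), and at a log2 fold change of at least 1 it was 2659 higher and 1520 lower. Zc3h12a stood at 0.52 ± 0.12 and Batf at 0.12 ± 0.06.

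Effector genes were higher in wild-type TIL for 23 of 25 and lower for 1, exhaustion genes for 16 and 3 of 19 with Pdcd1 at 5.08 ± 0.14, and residency genes for 10 and 1 of 12 with Prdm1 at 6.02 ± 0.21. Their adjusted p values were 4.57e-09, 1.52e-06 and 0.000262, and adjusted p = 0.14, 0.0597 and 0.14 with an estimated correlation. Naive and memory genes were lower for 21 of 22 and higher for 1, such as Klf3 (−3.17 ± 0.09) and Satb1 (−2.11 ± 0.08). Their adjusted p was 1.22e-08, and adjusted p = 0.14 with an estimated correlation. Mitotic genes were higher for 30 of 30, Mki67 by 3.01 ± 0.28, and S phase genes for 27 of 30 (27 and 1 lower adjusted over the list alone). These lists had adjusted p = 1.22e-08 and 2.02e-05, and adjusted p = 0.412 and 0.47 with an estimated correlation. Glycolysis rose in 20 of 22 genes and fell in 1, with rises such as Tpi1 (2.93 ± 0.09) and the lactate transporter Slc16a3 (4.59 ± 0.17). Glycolysis had adjusted p = 5.87e-09, and adjusted p = 0.153 with an estimated correlation. Ribosomal protein genes were lower for 53 of 54. The camera test gave adjusted p = 2.38e-12, and adjusted p = 0.285 with an estimated correlation. AP-1 and IRF factors (17 higher, 3 lower of 21), Regnase-1 targets (14 of 15 higher), cholesterol (17 and 3 of 21), interferon (16 and 3 of 27), interleukin-2 and STAT5 (12 and 4 of 18) and dissociation stress genes (18 and 1 of 20) were also called higher (adjusted p = 1.4e-05 to 0.00294), and adjusted p = 0.14 to 0.52 with an estimated correlation. Counts adjusted over the list alone were the same where no other is given.

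RNA of melanoma and macrophage markers was plain in the tumour libraries. All 12 melanoma genes were higher in wild-type TIL, the melanosome gene Pmel going from 12.4 to 83.9 CPM and Dct from 0.0625 to 60.8 CPM, and all 14 macrophage genes were higher, Lyz2 going from 13.8 to 50.4 CPM. NK cell genes were higher for 6 of 6, from NK cells or from the sorted CD8 T cells themselves, which was not tested. B cell genes were lower for 5 of 8. The adjusted p values were 4.61e-07, 1.73e-05, 0.000833 and 0.0389, and adjusted p = 0.14, 0.285, 0.0597 and 0.153 with an estimated correlation. The B cell call was lost without any of the 4 wild-type PLN replicates or TIL wild-type replicate 1, 3 or 4 (adjusted p = 0.0637 to 0.110), and with the stricter filter (adjusted p = 0.0562). NF-kappaB, the Bcl2 family, receptors, mitochondrial lists, nuclear RNA, dendritic cells, CD4 T cells, stroma, red cells and T cell identity were not called between tissues in wild type (adjusted p = 0.0523 to 0.855).

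**Figure D4:**
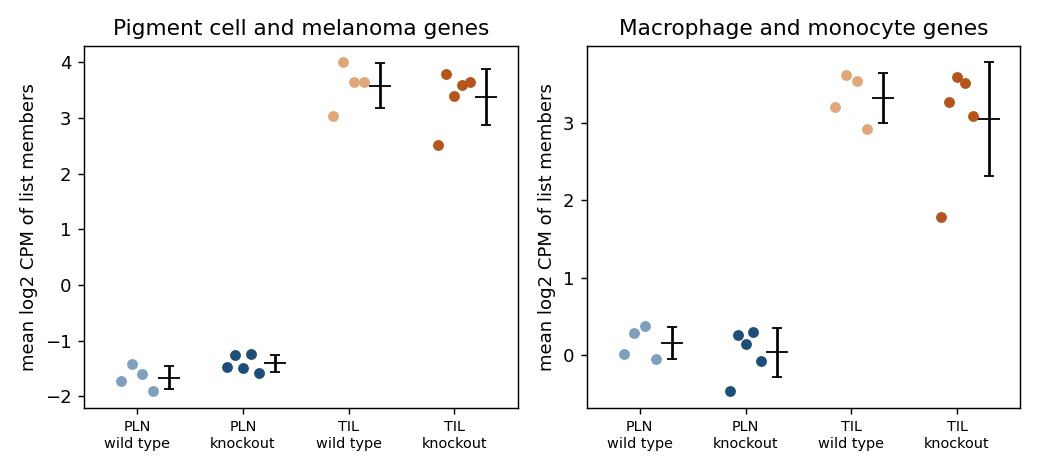
Mean log2 CPM of melanoma and macrophage marker lists in each library (dots) of the 4 groups, with the group mean and SD (black bars). Melanoma genes lie at −1.66 and −1.41 on average in PLN and at 3.58 and 3.38 in TIL (wild type and knockout), and both lists are lowest among TIL libraries in TIL knockout replicate 1 (2.52 and 1.79).

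Knockout cells from tumours and lymph nodes (n = 5 and 5 libraries) differed in 10422 genes, 5106 higher and 5316 lower in TIL. With size factors in place of TMM the balance turned (5395 higher, 4948 lower), and at a log2 fold change of at least 1 it was 1967 higher and 882 lower. The chemokines Ccl3 (7.20 ± 0.22) and Ccl4 (6.39 ± 0.16), Rgs16 (6.37 ± 0.18), Gp49a (5.72 ± 0.11) and Lilrb4 (5.22 ± 0.08) rose most among genes of the naming rule. The ganglioside enzyme St8sia1 (−4.48 ± 0.13), Fam101b (−3.87 ± 0.12), Itgae (−3.79 ± 0.14), Dtx1 (−3.64 ± 0.13) and the interleukin-6 receptor Il6ra (−3.27 ± 0.12) fell most among them. Batf was lower in TIL (−0.58 ± 0.05), and Zc3h12a stood at 0.09 ± 0.10, or −0.01 without TIL knockout replicate 3 (adjusted p = 0.918, in a range of 0.13 to 0.918 over all alternatives). Of genes changed between tissues in both genotypes, 8221 moved the same way and 336 in opposite ways, with r = 0.85 across genes. Exhaustion (16 higher and 2 lower of 19, Tigit 4.04 ± 0.12) and NK cell genes (5 of 6 higher) were called with the preset correlation (adjusted p = 1.98e-08 and 0.000608) and also held with an estimated correlation, each at adjusted p = 0.0311. Effector genes (20 and 3 of 25), naive and memory genes (1 and 19 of 22), glycolysis (21 and 1 of 22), residency (9 and 1 of 12), Regnase-1 targets (12 and 1 of 15) and AP-1 and IRF factors (16 and 4 of 21) were called in the same directions as in wild type (adjusted p = 1.07e-12 to 0.000608), and adjusted p = 0.128 to 0.195 with an estimated correlation. Dissociation stress (19 and 1 of 20), interleukin-2 and STAT5 (13 and 5 of 18), cholesterol (14 and 3 of 21) and B cell genes (1 and 7 of 8) were called too, with adjusted p = 7.34e-08, 0.000312, 0.0116 and 0.0311, and adjusted p = 0.148, 0.199, 0.547 and 0.138 with an estimated correlation. The B cell call was lost with the stricter filter (adjusted p = 0.0911). Mitotic genes were higher for 17 of 30 (15 adjusted over the list alone) without a call (adjusted p = 0.0733), and ribosomal protein genes gave 20 higher and 7 lower of 54 (18 and 7 adjusted over the list alone; adjusted p = 0.136). Macrophage genes were higher for 14 of 14, red cell genes for 5 of 5 and melanoma genes for 11 of 12, the other being lower (Trpm1, −1.03 ± 0.15, named after its value was seen). In the order melanoma, macrophage and red cell these lists had adjusted p = 3.05e-07, 1.03e-06 and 0.0311, and adjusted p = 0.138, 0.211 and 0.451 with an estimated correlation. The red cell call was lost without TIL knockout replicate 1 (adjusted p = 0.0564). Median, mean and test differed in sign for receptors, CD4 T cells and T cell identity, none of them called.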

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

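The tests of mitotic genes, of Zc3h12a, of B cell RNA, of Cd8a and of CD4 T cell RNA were chosen only after the results they bear on were seen, as was the tumour RNA covariate; the splits of the samples were planned.

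Knockout acted differently in the 2 tissues by the interaction test, in which 4366 genes differed. The median interaction of list members, on the log2 scale, was −1.95 for mitosis, −0.71 for S phase, −0.53 for tissue residency, −0.34 for cholesterol and −0.29 for the interferon response, and 0.70 for naive and memory genes and 0.65 for ribosomal proteins. Single genes stood at −5.48 (Cd244), −4.44 (Gzmb), −4.29 (Itga1), −3.97 (Chn2), −3.79 (S100a4), −0.70 (Batf) and −0.43 (Zc3h12a), and at 3.15 (Tnfrsf25), 3.01 (Cd83), 2.35 (Ccl4), 2.24 (Dtx1) and 2.14 (Cd22). Only 1 of 100 splits, the real one, gave as many interaction genes (4366 against at most 1740 in the others). These splits shuffled genotype in both tissues, which also breaks up a knockout effect common to both. They therefore cannot decide whether chance alone gave the number of interaction genes. Chance could not be excluded for the number of lists called in the interaction (7, with at most 13 in other splits and 56 of 100 as large).

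Mitotic genes were lower with knockout in TIL (median log2 fold change −0.83) and higher in PLN (0.97). Dividing tumour cells in the TIL libraries are argued against as the whole cause, because the median stayed at −0.67 with the tumour RNA index as a covariate and the list stayed called at the preset correlation. Without the covariate the call in TIL was lost with an estimated correlation (adjusted p = 0.804), and the exact permutation test of the levels per library gave p = 0.0556. A single library is argued against as well: the median nearest 0 when 1 library was left out was −0.59, without TIL wild-type replicate 3, and −0.63 without TIL knockout replicate 1. The labels name no batch, and each group has its own sample code, so a difference in handling between groups could not be told apart from genotype. An effect of genotype on division that differs between tissues stays open as untested.

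The Zc3h12a transcript was not lower in knockout libraries. Swapped genotype labels in 1 tissue are argued against by the correlation of knockout effects across genes (Pearson's r = 0.46, where a swap would make it negative). A swap in both tissues would leave that correlation unchanged, so such a swap was not tested. An edited transcript that is still counted stays open, since knockout TIL held 116% of the wild-type level and counts per gene cannot show a small edit; it may also be that the transcript rises when its protein is lost.

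Markers of other lymphocytes moved with knockout. RNA from B cells is argued against in TIL, because Cd79b rose by 2.58 more than its partner Cd79a (log2, standard error 0.24), which stood at −0.01 ± 0.21. Fewer CD8 T cells are argued against as the whole cause of lower Cd8a, because Cd8a fell by more than Cd8b1 in TIL (difference −0.50 ± 0.07). RNA from CD4 T cells in PLN stays open: Cd4 reached 9.40 CPM and Cd8b1 stood at −0.14, a fall so small that a few CD4 cells or a change within CD8 cells could give it. The cells had been sorted as CD8 T cells.

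Samples far from the rest of their group appeared in 6 of 148 tests, where chance gives about 5%, or 1 in 20, and 4 of the 6 were in TIL knockout replicate 1. In that library the mean log2 CPM was 1.79 for macrophage genes (3.08 to 3.59 in the other knockout TIL libraries), 2.25 for dendritic cell genes (3.06 to 3.21), 6.21 for AP-1 and IRF factors (6.48 to 6.58) and 4.65 for cholesterol genes (4.95 to 5.06). Interferon response genes stood at 6.28 in TIL wild-type replicate 1 (5.94 to 5.99 in the others), and the 10 most abundant genes held 8.01% of counts in PLN wild-type replicate 4 (8.65 to 8.71% in the others).

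Of 100 splits in TIL only the real one gave as many genes changed with knockout (5270 against at most 3854 in other splits). The same held in PLN (5680 against 3282) and between tissues in knockout (10422 against 5672), each with 100 splits. Between tissues in wild type it held with only 35 splits (11113 against 0). Chance is argued against as far as these numbers of splits allow. The splits cannot tell genotype or tissue from separate handling of the groups. Genes changed the same way in both tissues numbered 1943, against at most 338 in other splits. Those splits shuffled genotype in both tissues, so they cannot tell shared from unrelated knockout effects. Independent lists would already share 940. Chance could not be excluded for the number of lists called by camera. In TIL 8 were called, with up to 20 in other splits (76 of 100 as large), and in PLN 8, with up to 9 (10 of 100). Between tissues 18 were called in wild type, with up to 22 (13 of 35), and 15 in knockout, with up to 19 (41 of 100).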

How the results depend on the processing

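The alternatives that model tumour RNA were chosen only after the data were seen; the others were planned. Of 12022 values of 448 named-gene results under alternatives, 11933 kept direction and side of the threshold, 86 lost the call, 2 gained it (Zc3h12a in TIL: 0.29 without TIL knockout replicate 1, adjusted p = 0.0295, and 0.28 with no filter, adjusted p = 0.0383) and 1 turned (Zc3h12a in knockout TIL against PLN: −0.0115 without TIL knockout replicate 3, and up to 0.159 without TIL knockout replicate 1; the cause was not tested). A threshold of 1 on the log2 scale, which removes small changes by construction, left 842 genes in TIL, 1274 in PLN, 4179 between tissues in wild type, 2849 in knockout, 1163 in the interaction and 369 shared. Lists called with camera and an estimated correlation numbered 0, 0, 0, 2 and 0 in the order TIL, PLN, wild type, knockout and interaction (2, 2, 9, 9 and 2 at an unadjusted p under 0.05), and with fry, which tests a list without comparing it with other genes, 14, 19, 27, 21 and 11; the cause was not tested. Leaving out each library in turn gave 4394 to 5392 genes in TIL, 4870 to 6288 in PLN, 10597 to 11363 and 9834 to 10878 between tissues, 3802 to 4616 in the interaction and 1739 to 2117 shared, and 7 to 10, 6 to 9, 17 to 19, 15 to 16 and 6 to 9 lists. Without TIL knockout replicate 1 the counts were 5245, 6288, 11363, 10878 and 4458. DESeq2 called 5143 genes in TIL, 5006 of them shared with edgeR, and 5568 in PLN, 5414 of them shared. Fitting only the 2 groups compared gave 3536 genes in TIL and 7463 in PLN. Unlike the main model, that fit does not pool the spread of TIL and PLN libraries, and the cause of the shift was not tested. With the replicate number as a block the counts were 5154, 5594, 11096, 10434 and 4410, with 1911 shared, and 8, 8, 18, 16 and 6 lists. Under the block the B cell list in TIL (adjusted p = 0.0519) and the residency list in the interaction (adjusted p = 0.0589) were not called. Same-numbered libraries correlated at −0.16 to 0.31. Between genotypes 3 of 4 pairs in TIL and 1 of 4 in PLN were over 0.1, and between tissues 0 of 4 in wild type and 2 of 5 in knockout. Libraries that correlated best with their own number were 2 of 4, 3 of 4, 2 of 4 and 1 of 5 in that order. Not every pair was over 0.1, so the numbers were not taken to pair the samples; the correlations were a hint from the data, not the design. At these depths and numbers of libraries, which were not varied, the simulated test recovered 46% of genes changed 1.3-fold in TIL and 28% in PLN. The simulated spread was the same in all groups, so these shares do not rank the tissues.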

Other observations

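The genes in the first paragraph were chosen after their values were seen; the tests of stem-loops and of the type 2, follicular helper and NK receptor lists had their predictions written before their results were seen.

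The following genes outside the lists changed with knockout in at least 1 tissue. Il13, a type 2 cytokine, rose by 5.84 ± 0.41 in TIL, to 27.7 CPM, the stem cell factor receptor Kit by 4.16 ± 0.11 in TIL and 4.73 ± 0.11 in PLN, and the skin-homing receptor Ccr10 by 3.26 ± 0.27 and 4.82 ± 0.20. The hypoxia-inducible factor Epas1 rose by 4.69 ± 0.24 in TIL, from 3.39 to 83.2 CPM, and 3.50 ± 0.33 in PLN, the integrin Itgb5 by 3.99 ± 0.18 and 4.70 ± 0.23, and the B cell factors Pou2f2 by 2.90 ± 0.15 and 2.45 ± 0.14 and Spib by 2.36 ± 0.26 and 4.55 ± 0.20. The interleukin-9 receptor gene Il9r rose in PLN (6.95 ± 0.17, from 0.482 to 59.1 CPM) and stood at 0.35 ± 0.39 in TIL (adjusted p = 0.538), with an interaction of −6.60 ± 0.59 (adjusted p = 7.2e-08). Klre1, Klrd1 and Klrc3, genes of NK receptors, fell in both tissues, Klre1 by 3.16 ± 0.09 and 2.39 ± 0.17, Klrd1 by 1.33 ± 0.08 and 1.84 ± 0.09, and Klrc3 by 2.05 ± 0.15 and 1.05 ± 0.19. The TGF-beta binding receptor Lrrc32 fell by 3.54 ± 0.30 in TIL and the interleukin-10 receptor Il10ra by 1.13 ± 0.08 in TIL and 1.02 ± 0.08 in PLN.

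Lists written for these patterns, without the genes that prompted them, were counted with exact Clopper-Pearson intervals at 95%. The intervals treat genes as independent, which genes measured in the same libraries are not. They may therefore be too narrow, and they do not measure the spread between samples. Of 11 follicular helper genes 8 rose in TIL (72.7%, 39.0 to 94.0%; 17.8% of all genes), including Il21 (1.71 ± 0.29), Tnfsf8 (2.003 ± 0.149) and Sostdc1 (3.24), and 2 fell (Pou2af1 −1.35, Folr4 −0.43). In PLN 3 rose (27.3%, 6.02 to 61.0%) and 2 fell (Pou2af1 −0.55, Il6st −0.53). A wider rise of such genes in TIL may hold, while PLN stays open. Of 8 type 2 genes 5 rose in PLN (62.5%, 24.5 to 91.5%; 19.4% of all genes), including the interleukin-33 receptor Il1rl1 (2.65 ± 0.25) and Gata3 (0.44 ± 0.08), with Gpr44 at −0.76 ± 0.36 (adjusted p = 0.109) and Il17rb at −0.48 ± 0.20 (adjusted p = 0.0646). In TIL 2 rose (25.0%, 3.19 to 65.1%) and 2 fell (Gpr44 −1.26, Il10 −0.81). A wider rise of type 2 genes may hold in PLN, while TIL stays open. Of 12 NK receptor genes 8 fell in TIL (66.7%, 34.9 to 90.1%, against 15.01% of all genes), including Klrc2 (−1.48) and Klrk1 (−1.37), and 1 rose (Fcer1g 0.95). The 8 include Klrc1 (−1.68), already named in the Results among the largest falls in TIL. In PLN 4 fell (33.3%, 9.92 to 65.1%) and 2 rose (Klrb1a 1.47, Fcer1g 1.01), with Klrc1 at 0.15 ± 0.12 and Klrc2 at 0.10 ± 0.12, so a wider fall in PLN stays open. These receptors have near-identical copies, so reads could have been shared among them.

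Genes that rose in both tissues might carry the stem-loops that Regnase-1 is known to cleave. The UTRs came from a GENCODE annotation of another mouse build than the mm9 of the counts, matched by gene symbol alone, so that unmatched symbols count as not searched. Of 1251 such genes 1076 had a 3' UTR to search, and 68.7% of these carried a stem with a pyrimidine-purine-pyrimidine loop against 63.5% of other genes, with longer UTRs (median 1384 against 1145 bases). Adjusted for length, GC content and expression, the odds ratio was 1.06 (95% interval 0.898 to 1.25) and that of a mirrored control loop 1.02 (0.865 to 1.204). Genes that fell in both tissues carried the loop as often (68.7% of 527 searched, against 63.7% of other genes), with an odds ratio of 0.943 (0.748 to 1.19). The crude excess was therefore not specific to genes that rose, and the adjusted interval leaves a small link open.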
